A study of Mus musculus with 24 samples.

How the data were processed

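RNA from whole mouse lungs was made into libraries with the Illumina TruSeq RNA kit at each stage, per the labels' protocols. STAR 2.5.3a, RSEM 1.3.0, edgeR and the mm10 genome are named in the submitters' processing notes, without their roles. The annotation, the strand setting and any filter are not given in the sources used here. The deposited table holds RSEM expected counts per gene, which were whole numbers as deposited, for 51912 genes in 24 libraries. RSEM assigns reads that match several genes by estimated shares, so counts of near-identical copies and of overlapping genes on opposite strands are uncertain. Gene symbols are those of the table, 102 of which occur more than once, and 51633 identifiers were found in the GENCODE annotation of GRCm38 (mm10), which gave coordinates.

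Libraries were grouped by genotype and stage from their titles, which call them biological replicates, and table columns were matched to them by the identifier in the labels. Totals ran from 27.02 to 36.35 M counts, so that 1 CPM equals 27.02 to 36.35 counts and counting error weighs most for genes near 0, such as Gm9008 in CKO lungs. The 10 most abundant genes took 4.83 to 7.25% of counts. A chi-square statistic per gene between libraries of a group was 20.3 or more, so no pair differed by as little as sampling noise. CPM values use library sizes scaled by the trimmed mean of M values (TMM), whose factors ran from 0.892 to 1.05.

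Before the data were examined, the tests, the alternatives, 41 gene lists (982 genes, 953 in the table) and the rule for naming genes were fixed. At each stage the 4 control and 4 CKO libraries were fitted alone with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM, robust dispersions and the quasi-likelihood test (glmQLFit, glmQLFTest), and p was adjusted by Benjamini-Hochberg, with calls at adjusted p under 0.05. Differences between stages were interaction contrasts in one fit of 24 libraries with 6 groups. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all lists and stages, and again with an estimated correlation and with fry, which tests for change in one direction or in either. The median log2 fold change over all genes was -0.01 at E16, -0.02 at P0 and -0.01 at P3.

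Named genes were, per stage, Sin3a and Sin3b, the 6 higher and 6 lower called genes with the largest change at a mean log CPM of at least 1 and no overlap between genotypes, and up to 3 members with the smallest p of each list described. For all stages the rule took up to 5 genes per direction, and for each interaction the 3 genes with the smallest p per direction. Sex-linked markers and predicted loci were passed over in its ranked parts. The average over stages, with its lists and genes, was added after the per-stage counts were seen, as were sample quality weights, an Xist covariate, the fits without libraries high in thymus markers and the counts without genes near Sin3a.

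Alternatives were median-of-ratios scaling, library size only, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersions, erythroid genes removed, the replicate number or the identifier prefix as a block, and each library left out in turn. All 35 splits of the 8 libraries of a stage were refitted, 60 drawn splits for fits of 24 libraries and 100 drawn combinations for overlaps between stages. Transcripts of 3 loci were compared with all others by BLAST 2.17.0.

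The fits were tested on simulated counts with known changes. Genes changed 2-fold were recovered in 86.6% of cases at E16, 14.9% at P0, 85.1% at P3, 31.3% for the difference between E16 and P0 and 97.0% for the stage average. For 1.5-fold changes the shares were 29.9%, 0%, 34.3%, 2.99% and 64.2%. Each share rests on 67 genes in a single run. Changes were given only to genes above a minimum mean count, and counts were drawn gene by gene, without differences that many genes of a library share. The shares may therefore be lower in the real libraries.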

Results

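RNA was sequenced from whole mouse lungs in which Sin3a, the scaffold of a histone deacetylase corepressor complex, carried floxed alleles. Cre was made from a tetO promoter by the Tbx4-rtTA transactivator, which is active in lung mesenchyme, once doxycycline was fed to the dams from embryonic day 12. There were 24 libraries in 6 groups, with 4 control and 4 conditional knockout (CKO) lungs at each of 3 stages, namely embryonic day 16 (E16), the day of birth (P0) and postnatal day 3 (P3). Titles give the control genotype as 1 floxed Sin3a allele at E16 and P0, and as homozygous floxed at P3. Both transgenes are named in the titles of controls as well, so by title P3 controls have the genotype of P3 CKO lungs. The groups at P3 were assigned from the words control and CKO alone. The predicted locus Gm9008, lower in CKO lungs at E16 and P0, also parted these P3 groups (2.81 to 4.73 CPM in controls, 0 to 0.178 in CKO lungs). It does not measure the Sin3a genotype of the P3 controls. Library totals ran from 27.02 to 36.35 M counts, and 21574 to 24313 genes had at least 1 count in a library. Levels are CPM, counts scaled to a library of 1 M counts, given as mean ± SD over 4 libraries, and log2 fold changes are CKO minus control ± SE.

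Sin3a (ENSMUSG00000042557, mm10 chromosome 9, 57072040 to 57128366) was not lower in the CKO lungs. At E16 it ranged from 125 to 141 CPM in controls and from 105 to 144 CPM in CKO lungs, at P0 from 85.6 to 105 CPM and from 85.9 to 112 CPM, and at P3 from 89.3 to 102 CPM and from 99.2 to 107 CPM. Its log2 fold changes were -0.03 ± 0.10, 0.09 ± 0.15 and 0.08 ± 0.07, with adjusted p of 0.956, 0.989 and 0.657 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At E16 the sign turned when CKO replicate 3 was left out, to 0.05. A whole-gene count also takes reads from exons outside a floxed segment and from cells without Cre, so these totals do not check the genotype labels. By title, E16 and P0 controls carry both transgenes too and can lose their floxed allele in the same cells. If those titles hold, CKO lungs of these stages were set against lungs with a heterozygous deletion. The paralog Sin3b had log2 fold changes of 0.18 ± 0.09, 0.35 ± 0.20 and 0.24 ± 0.09, which did not pass at any single stage (adjusted p = 0.514, 0.878 and 0.240, edgeR).

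**Figure D1:**
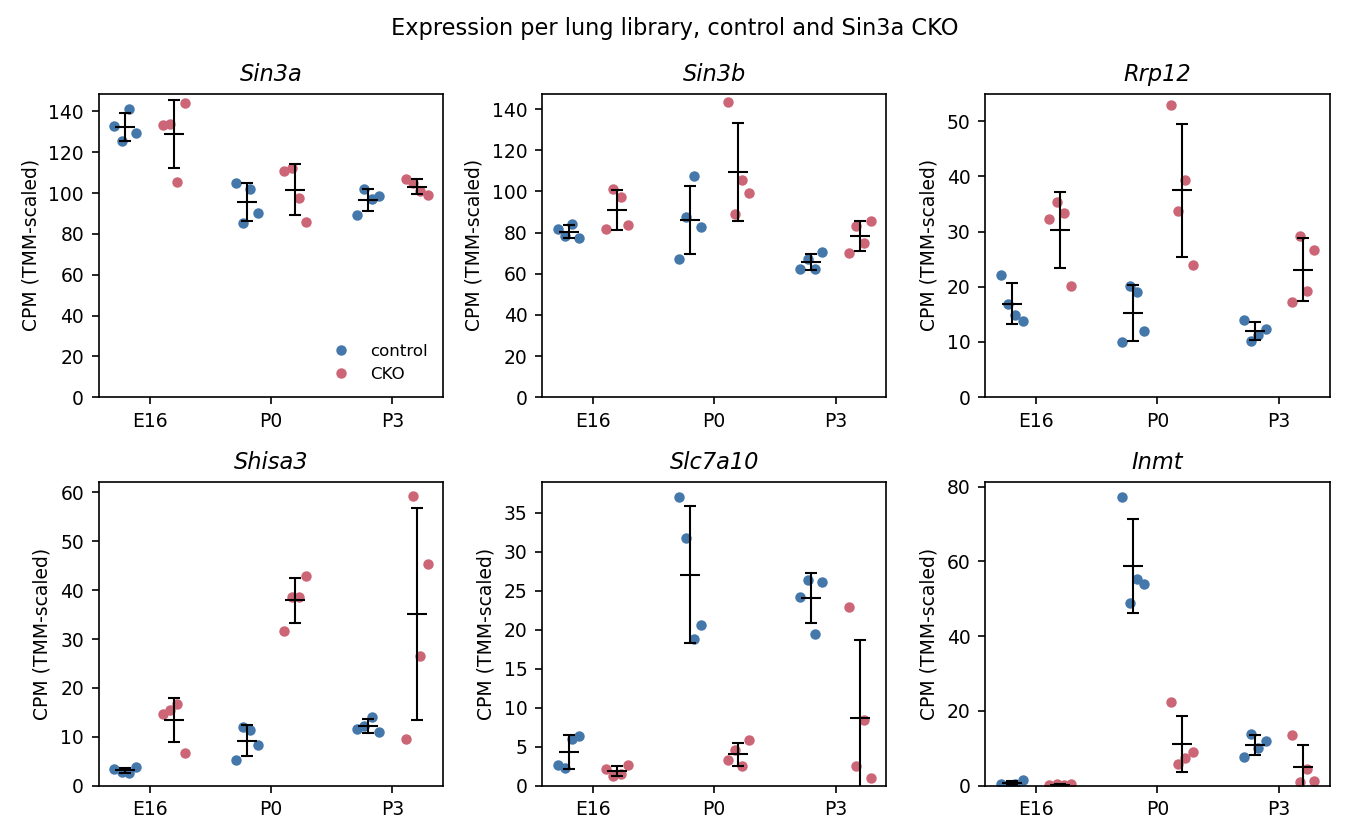
CPM of 6 genes (y axis) in each library by stage (x axis), controls in blue and CKO lungs in red, with bars for the mean ± SD of 4 libraries. Sin3a totals overlap between genotypes at all 3 stages, and P0 Shisa3 and Slc7a10 levels do not.

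At E16, the series' question is which genes differ between CKO and control lungs after induction from embryonic day 12. Of 16606 genes tested, 0 were higher and 3 were lower, all of them predicted loci chosen for naming after their values were seen. Gm26825 was 201 ± 8.8 CPM in controls and 3.52 ± 0.90 in CKO lungs, a log2 change of -5.84 ± 0.17 (adjusted p = 3.66e-07, edgeR). Gm15459 was 150 ± 4.1 and 21.7 ± 1.8 CPM, a change of -2.79 ± 0.08 (adjusted p = 3.66e-07, edgeR). Gm9008 was 6.26 ± 1.43 CPM in controls and 0.017 ± 0.019 in CKO lungs (adjusted p = 0.000102, edgeR). Gm26825 and Gm15459 lie on opposite strands of one segment of chromosome 5 (5781530 to 5783636 and 5781615 to 5783555), and both are near-identical to Hspa8 transcripts, as Gm9008 (chromosome 6, 76495432 to 76497784) is to Rnf26, so how reads were shared among them is uncertain.

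At E16 no member of the gene groups fixed beforehand passed over all genes tested. In the list of MYC targets and ribosome biogenesis, 26 of 29 members had a positive change, with a mean of 0.27 and 5 members past the test adjusted over the list alone. Its members Nop16 (27.7 ± 2.7 and 39.3 ± 5.6 CPM) and Rrp12 (16.9 ± 3.7 and 30.3 ± 6.9 CPM), both nucleolar ribosome assembly factors, had changes of 0.50 ± 0.11 and 0.84 ± 0.21. DNA replication genes were positive for 33 of 34 members (mean 0.23, 2 past the test adjusted over the list alone). Members of the SIN3 and histone deacetylase complexes were positive for 20 of 28 (mean 0.11, 1 past the test adjusted over the list alone), led by Ing2 at 0.72 ± 0.14 and Sap30 at 0.46 ± 0.13. All 15 pericyte markers (mean -0.34), all 21 alveolar type 1 markers (mean -0.27) and 23 of 29 alveolar fibroblast markers (mean -0.25), among them Mfap4 (-0.66 ± 0.19) and Rarres2 (-0.89 ± 0.29), were negative, and adjusted over the list alone 0, 1 and 0 of them passed. Camera with a preset correlation of 0.01 called these 6 lists, at adjusted p of 1.83e-09, 1.06e-10, 0.00448, 3.03e-05, 0.000309 and 0.00147, among 15 of 38. With an estimated correlation none was called (lowest adjusted p = 0.412), nor with the directional fry test (lowest adjusted p = 0.139). The other lists called were p53 targets (mean 0.17), ribosomal proteins (0.14), mitosis (0.08) and erythroid genes (0.27), and alveolar type 2 (-0.23), smooth muscle (-0.18), FGF signalling (-0.17), endothelial (-0.13) and matrix genes (-0.11), and adjusted over the list alone 3 p53 targets and 0 of the rest passed. Erythroid genes had a mean of 4.49 log2 CPM in CKO replicate 3, against 3.82 to 4.10 in the other CKO lungs and 3.69 to 4.14 in controls. Much of their rise rests on this library.

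At an unadjusted p under 0.05, 1749 E16 genes differed where uniform p-values would give 830.3, 1091 higher and 658 lower, but other splits of the same 8 libraries gave up to 3272 and the fit of all 24 libraries gave 944. There were 1099 without CKO replicate 2 and 1135 without control replicate 3. The CKO and control libraries did not overlap in 5.91% of genes (2.86% by chance). DESeq2 called 295 genes, 235 of them higher, and limma-voom called 3, 0 of them higher. Leaving out CKO replicate 4 gave 188 calls, 120 higher and 68 lower, and leaving out control replicate 4 gave 10. Xist exceeded 100 CPM in 1 of 4 control and 4 of 4 CKO libraries, so sex was unequal between these groups.

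At P0, 17198 genes were tested, 2 were higher in CKO lungs and 5 were lower. Shisa3 (chromosome 5, 67607882 to 67623552), which encodes a membrane-associated inhibitor of WNT and FGF receptor maturation, rose from 9.22 ± 3.15 to 38.0 ± 4.6 CPM, a log2 change of 2.05 ± 0.27 (adjusted p = 0.0425, edgeR). Slc7a10 (chromosome 7, 35186385 to 35201114), an amino acid transporter gene listed here among alveolar fibroblast markers, went from 27.1 ± 8.8 to 4.04 ± 1.46 CPM, a change of -2.74 ± 0.34 (adjusted p = 0.0352, edgeR). The complement gene C3 (chromosome 17, 57203970 to 57228136) went from 469 ± 97 to 169 ± 20 CPM, a change of -1.47 ± 0.18 (adjusted p = 0.0366, edgeR). Each of these was separated between all 4 control and all 4 CKO libraries. The remaining calls, named after their values were seen, were Gm26825 (160 ± 6.4 and 3.20 ± 0.93 CPM), Gm15459 (88.7 ± 10.3 and 15.8 ± 1.6 CPM), Gm9008 (3.90 ± 0.23 and 0.018 ± 0.020 CPM) and Gm26675, which had 0 counts in all 4 controls and 2.00 ± 0.57 CPM in CKO lungs. Gm26675 was not absent from controls at other stages, with 0.034 to 3.30 CPM at E16 and 0 to 1.39 at P3. CKO lungs had 0.94 to 5.12 CPM at E16 and 0 to 2.03 at P3, so its levels overlapped there.

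At P0, 1 listed gene alone, Slc7a10, passed over all genes tested. Of 29 alveolar fibroblast markers 23 were negative (mean -0.44, 5 past the test adjusted over the list alone), and Inmt, a methyltransferase gene of this list, had 58.8 ± 12.6 CPM in controls and 11.1 ± 7.6 in CKO lungs (-2.40 ± 0.41, adjusted p = 0.143, edgeR). Interferon response genes were negative for 29 of 30 members (mean -0.51), pericyte markers for 12 of 15 (mean -0.38; Cox4i2 -1.04 ± 0.28) and capillary and general endothelial markers for 27 of 29 (mean -0.31). MYC targets and ribosome biogenesis genes were positive for 26 of 29 (mean 0.40), with Rrp12 at 15.3 ± 5.0 and 37.5 ± 12.1 CPM and Fbl at 0.82 ± 0.21, and adjusted over the list alone 2 of them and 0 of the interferon, pericyte and endothelial genes passed. Acta2, the smooth muscle actin gene, had 405 ± 119 and 1316 ± 346 CPM (1.71 ± 0.28, adjusted p = 0.126, edgeR), while its list of smooth muscle and myofibroblast genes had 15 positive and 9 negative members and 1 past the test adjusted over the list alone. Camera called the 5 lists with adjusted p of 5.42e-08, 5.07e-08, 0.00334, 4.34e-05 and 1.83e-09, among 14 of 40, and with an estimated correlation the lowest adjusted p was 0.412 (0.212 with directional fry). In fry's test of change in either direction alveolar fibroblast and mesothelium lists were called (adjusted p = 0.0453 for both). Mesothelial markers were negative for 10 of 14 (mean -0.47, camera adjusted p = 6.05e-05, 6 past the test adjusted over the list alone) and neutrophil markers for 16 of 17 (mean -0.42, 0.00159, 0 past it), with adjusted p of 0.412 and 0.550 with an estimated correlation. Macrophage and monocyte markers were positive for 19 of 27 (mean 0.24, camera adjusted p = 0.000899), with 0 past the test adjusted over the list alone and an adjusted p of 0.550 with an estimated correlation. Camera also called neuroendocrine and neuronal (mean 0.83), ribosomal protein (0.24) and mitosis genes (0.24), and lymphatic endothelial (-0.33), alveolar type 1 (-0.26) and alveolar type 2 markers (-0.21), and adjusted over the list alone 1 lymphatic gene and 0 of the rest passed. Neuroendocrine and neuronal genes had a mean of 2.68 log2 CPM in CKO replicate 3. Their mean was 0.11 to 0.84 in the other CKO lungs and 0.04 to 1.04 in controls, so their rise rests largely on this library. DNA replication genes (17 of 34 positive, mean 0.04), SIN3 complex members (18 of 28, mean 0.07) and p53 targets (17 of 32, mean 0.06) were not called at P0, at camera adjusted p of 0.157, 0.0935 and 0.175, with 0, 0 and 1 past the test adjusted over the list alone. Differences between stages were not tested for lists.

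Thymus and cartilage markers differed among P0 libraries. Thymus markers had a mean of 5.85 log2 CPM in control replicate 3 and 5.29 in CKO replicate 1, against -2.26 to -0.81 in the other P0 libraries, and cartilage markers had a mean of 4.14 in CKO replicate 3. Spread between replicates was widest at this stage (biological coefficient of variation 0.389, against 0.215 at E16 and 0.188 at P3), and 1107 genes had an unadjusted p under 0.05 where uniform p-values would give 859.9, other splits up to 2531 and the fit of all 24 libraries 2636. DESeq2 called 190 genes, and one fit of all 24 libraries called 264. The count fell to 4 without both libraries high in thymus markers, to 3 without control replicate 2, control replicate 4, CKO replicate 3 or CKO replicate 4, and to 4 without CKO replicate 1 or CKO replicate 2. Shisa3, Slc7a10 and C3 lost their calls in 13, 11 and 11 of their alternative fits.

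At P3, 17113 genes were tested, 0 were higher and 2 were lower. Gm9008 had 3.71 ± 0.79 CPM in controls and 0.066 ± 0.078 in CKO lungs (-5.80 ± 0.49, adjusted p = 0.00298, edgeR). AC160637.1 (chromosome 9, 59672814 to 59676700), a transcript still to be experimentally assigned, had 23.9 ± 1.4 and 12.5 ± 1.0 CPM (-0.94 ± 0.11, adjusted p = 0.0224, edgeR). Both were named after their values were seen. AC160637.1 lies within 25 Mb of Sin3a. It was also lower at E16 and P0 at an unadjusted p under 0.05 (edgeR), though not called, with log2 changes of -0.99 and -0.93. A local effect, taken up below, stays open for it. All 16 neutrophil markers were negative (mean -0.96), and 15 passed the test adjusted over the list alone while 0 passed over all genes. Among them, the granule protein gene Ngp had 35.3 ± 9.6 and 15.3 ± 4.0 CPM (-1.23 ± 0.24) and the receptor gene Csf3r had 25.6 ± 4.7 and 15.5 ± 2.6 CPM (-0.74 ± 0.16).

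MYC targets and ribosome biogenesis genes at P3 were positive for 27 of 29 members (mean 0.31), and 12 passed the test adjusted over the list alone, with Rrp12 at 0.93 ± 0.18 and Srm, the spermidine synthase gene, at 0.65 ± 0.12. All 32 cytosolic ribosomal protein genes were positive (mean 0.24) and all 30 capillary and general endothelial markers were negative (mean -0.32), with 3 and 5 past the test adjusted over the list alone. SIN3 and histone deacetylase complex members were positive for 22 of 28 (mean 0.16, 5 past the test adjusted over the list alone), with Sap130 at 0.48 ± 0.10 and Ing1 at 0.46 ± 0.10. Of 29 alveolar fibroblast markers 18 were negative and 11 positive (camera adjusted p = 0.130), and 9 passed adjusted over the list alone, 3 of them higher, Pdgfra among the former at -0.49 ± 0.14. Camera called the neutrophil, MYC, ribosomal protein, endothelial and SIN3 lists at adjusted p of 2.29e-18, 1.15e-11, 5.43e-11, 1.06e-10 and 0.000566, among 17 of 40, and with an estimated correlation the lowest adjusted p was 0.412 (0.139 with directional fry). Fry's test of change in either direction called the germline and MYC lists (adjusted p = 0.0453 and 0.0487). Camera also called lymphocyte markers, negative for 26 of 27 (mean -0.58), alveolar type 1 markers, negative for 21 of 21 (mean -0.26), and mitosis genes, positive for 32 of 32 (mean 0.23), at adjusted p of 1.76e-06, 3.89e-06 and 9.90e-07. With an estimated correlation their adjusted p was 0.519, 0.593 and 0.594, and 0 members of each passed the test adjusted over the list alone. The other lists called were DNA replication (mean 0.16), p53 targets (0.14) and hypoxia response (0.12), and secretory airway (-0.39), mast cell (-0.28), interferon response (-0.27), immediate early (-0.25), mesothelial (-0.24) and lymphatic endothelial genes (-0.20). Adjusted over the list alone 7 hypoxia response, 2 mast cell, 1 DNA replication and 1 p53 target genes passed, and 0 of the rest.

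At an unadjusted p under 0.05, 2634 P3 genes differed where uniform p-values would give 855.65, 1417 higher and 1217 lower, but other splits of the same libraries gave up to 4225 and the fit of all 24 libraries gave 1382. There were 4630 without CKO replicate 1 and 1513 without CKO replicate 2. No overlap between genotypes was seen for 7.46% of genes. The number of P3 calls changed most with CKO replicate 1, and it also changed with the test and with Xist as a covariate (121 calls). Without CKO replicate 1, 1625 genes passed (992 higher, 633 lower), without control replicate 1 there were 13, and without control replicate 2, 3 or 4 or CKO replicate 3 there was 1. DESeq2 called 601 genes, 407 of them higher, limma-voom called 2, 0 of them higher, and limma-voom with sample quality weights, added after this library was seen to stand apart, called 1162.

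**Figure D2:**
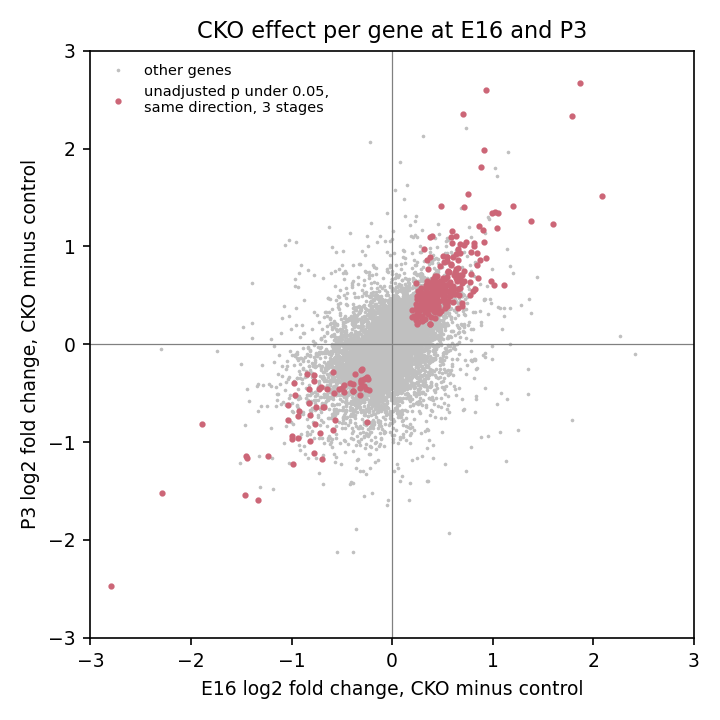
Log2 fold change (CKO minus control) of each gene at E16 (x axis) against P3 (y axis), for 16108 genes tested at both stages, of which 5 lie outside the axes. Red points are genes with an unadjusted p under 0.05 in one direction at all 3 stages, and Pearson r across all genes was 0.52.

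No library was shared between stages, so a change seen at more than 1 stage was measured independently. Across genes, which are not independent replicates, log2 fold changes correlated at r = 0.44 (rho = 0.50) between E16 and P0, 0.47 (0.52) between P0 and P3 and 0.52 (0.55) between E16 and P3, and 70.6%, 70.8% and 72.9% of genes had one sign in both. Gm9008 was the 1 gene called lower at all 3 stages. At an unadjusted p under 0.05 in one direction at each stage there were 250 higher and 66 lower genes among 15948, where independent lists would share 3.34 and 1.33.

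A fit of all 24 libraries with stage as a block and 1 genotype term was therefore added after the per-stage counts were seen to be small. It does not replace them, and its genes were chosen after the data were seen. By title it also pools heterozygous floxed controls at E16 and P0 with homozygous floxed ones at P3. It called 1544 of 18415 genes by edgeR's quasi-likelihood test, 991 higher and 553 lower in CKO lungs. Among those rising were Cyp46a1 (cholesterol 24-hydroxylase, 2.48 ± 0.29, adjusted p = 1.67e-05), the eosinophil chemokine gene Ccl11 (1.92 ± 0.35, 0.00138), Shisa3 (1.88 ± 0.22, 1.37e-05), Ly86 (1.75 ± 0.32, 0.00125), the nuclear receptor gene Rorb (1.68 ± 0.33, 0.00287) and the germline gene Asz1 (1.67 ± 0.29, 0.000824). Among those falling were Serpina3c (-1.86 ± 0.37, 0.00292), the WNT agonist gene Rspo4 (-1.81 ± 0.26, 0.000197), Slc7a10 (-1.80 ± 0.37, 0.00360), Inmt (-1.68 ± 0.40, 0.0105), Slc36a2 (-1.66 ± 0.29, 0.000991) and Cacnb4 (-1.59 ± 0.35, 0.00616). At least a doubling or halving was seen in 52 higher and 57 lower genes.

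In the stage average, 9 of 29 MYC targets and ribosome biogenesis genes rose, 0 fell and 20 did not pass. Adjusted over the list alone 17 rose, as did 22 ribosomal protein, 9 SIN3 complex, 7 p53 target and 5 DNA replication genes. Rrp12 rose by 1.02 ± 0.15 (adjusted p = 0.000182, edgeR), Nop16 by 0.53 ± 0.09 (0.000620) and Fbl, the nucleolar methyltransferase fibrillarin, by 0.64 ± 0.11 (0.000676). Of 32 cytosolic ribosomal protein genes 9 rose, 0 fell and 23 did not pass, Rps19 (0.28 ± 0.07) and Rps3 (0.22 ± 0.06) among those that rose. Of 28 SIN3 and histone deacetylase complex members 6 rose and 0 fell, and these were Ing1 (0.42 ± 0.07), Ing2 (0.48 ± 0.10), Sap130 (0.40 ± 0.07), Sap30 (0.58 ± 0.13), Sap30l (0.36 ± 0.07) and Sin3b (0.26 ± 0.08, adjusted p = 0.0369, edgeR). Of 33 p53 targets 7 rose and 0 fell, among them the receptor gene Eda2r (1.38 ± 0.21), the nuclease gene Aen (0.65 ± 0.11) and Psrc1 (0.97 ± 0.20). Of 34 DNA replication genes 4 rose, including the cyclin gene Ccne1 (1.29 ± 0.20) and the chromatin assembly gene Chaf1b (0.55 ± 0.12), while 0 of 32 mitosis genes passed, over all genes or adjusted over the list alone, though camera called their list (mean 0.18, adjusted p = 0.00209). Its adjusted p was 0.793 with an estimated correlation.

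In the average, of 29 alveolar fibroblast markers 10 fell, 1 rose and 18 did not pass, with Rarres2 at -0.87 ± 0.18, Scube2 at -0.76 ± 0.18, Mfap4 at -0.49 ± 0.14 and the growth factor gene Fgf10 at -0.35 ± 0.08 beside Slc7a10 and Inmt. Of 15 pericyte markers 2 fell, Cox4i2 (-0.66 ± 0.16) and Vtn (-0.96 ± 0.27). Of 30 capillary and general endothelial markers 4 fell, Kit (-0.31 ± 0.09), the angiopoietin receptor gene Tek (-0.31 ± 0.09), the transcription factor gene Foxf1 (-0.40 ± 0.12), which mesenchyme also expresses and which the alveolar fibroblast list holds too, and the tight junction gene Cldn5 (-0.50 ± 0.16). Of 17 neutrophil markers 6 fell, including the granule genes Ngp (-0.95 ± 0.17), Camp (-0.84 ± 0.20) and Ltf (-0.88 ± 0.24), and of 31 interferon response genes 5 fell, including Gbp2 (-0.42 ± 0.11), Bst2 (-0.44 ± 0.12) and Ifit1 (-0.84 ± 0.24). Fgf10 and Fgf2 (-0.40 ± 0.11) were the 2 of 19 FGF signalling genes that fell, and Pdpn (-0.38 ± 0.10) was the 1 of 21 alveolar type 1 markers. Smooth muscle and myofibroblast genes (mean -0.06, camera adjusted p = 0.773) and macrophage and monocyte markers (mean 0.09, camera adjusted p = 0.354) were not called. Adjusted over the list alone 12 alveolar fibroblast, 2 pericyte, 5 endothelial, 9 neutrophil, 9 interferon response, 3 FGF signalling and 1 alveolar type 1 genes fell.

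Camera called 15 of 40 lists in the average, 6 higher and 9 lower, with adjusted p of 1.23e-12 for the MYC list, 7.67e-11 for ribosomal proteins, 0.000377 for the SIN3 list, 0.00987 for p53 targets, 0.00132 for DNA replication, 0.000153 for alveolar fibroblasts, 0.00172 for pericytes, 7.12e-07 for endothelium, 1.64e-06 for neutrophils and 1.32e-05 for interferon response. With an estimated correlation adjusted p was 0.192, 0.431, 0.192, 0.293, 0.743, 0.431, 0.431, 0.431, 0.293 and 0.431 in that order, and no call of the 15 held. The other lists called were mitosis and, lower, FGF signalling (mean -0.15, camera adjusted p = 0.00987), alveolar type 1 (-0.26, 2.34e-05), alveolar type 2 (-0.18, 0.00247) and mesothelial genes (-0.24, 0.0119), with adjusted p of 0.452, 0.452, 0.546 and 0.452 with an estimated correlation for the last 4. Directional fry called 9 lists, DNA replication not among them (adjusted p = 0.325), and fry's test of change in either direction called 24, DNA replication among them (adjusted p = 0.0452). Without P3 CKO replicate 2 the average called 981 genes, and with the prefix of the library identifier, whose meaning the labels do not state, as a block it called 2871. That block gave 3, 7 and 1 calls at E16, P0 and P3. Each prefix held 1 to 3 libraries of a genotype, and no fit was made within a single prefix.

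**Figure D3:**
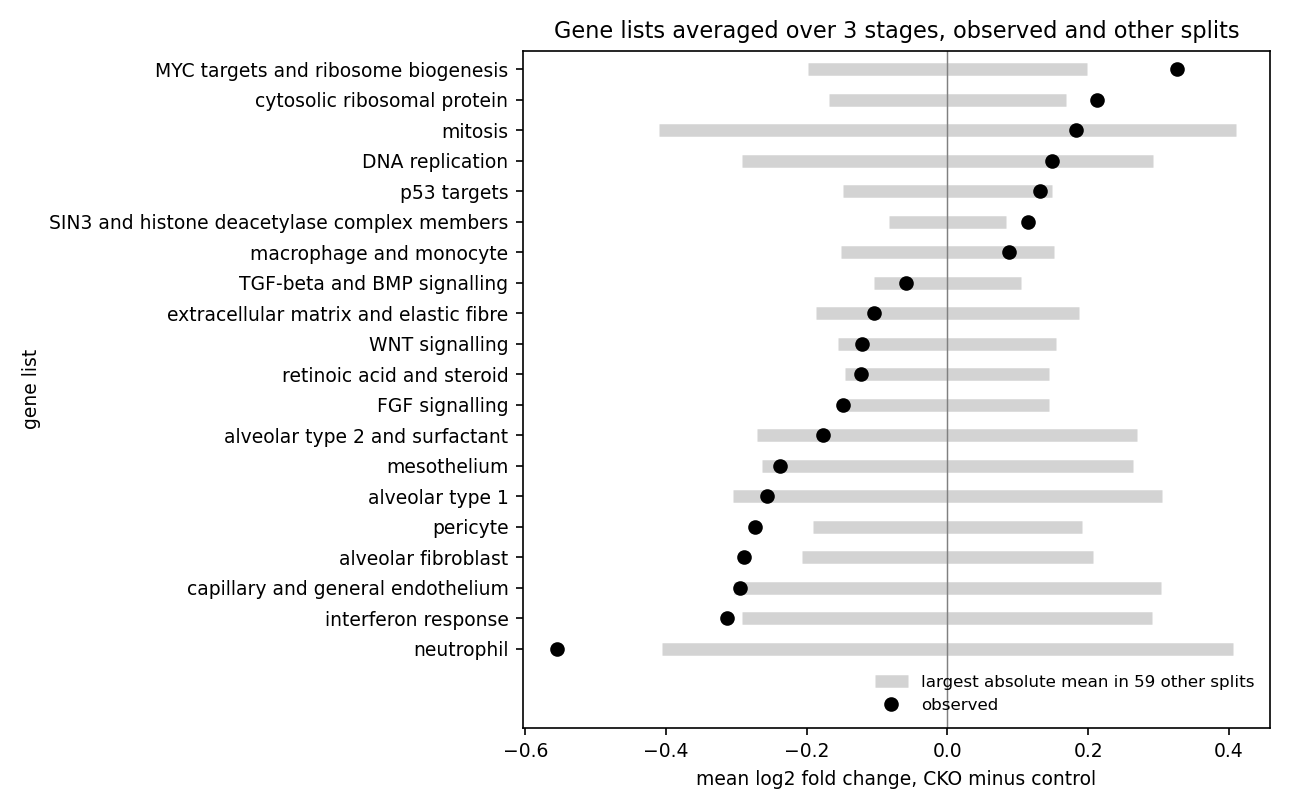
Mean log2 fold change (CKO minus control, x axis) of gene lists (y axis) in the average over 3 stages, for the lists whose mean was matched by at most 12 of 60 drawn splits. Grey bars span the largest absolute mean of the other drawn splits, and the MYC list at 0.33 and the neutrophil list at -0.56 lie outside them.

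The CKO effect itself was compared between stages in one fit of 24 libraries. By title P3 controls differ in genotype from E16 and P0 controls, so comparisons with P3 cannot tell age from control genotype. By edgeR 0 of 18415 genes differed between E16 and P0, 0 between P0 and P3 and 0 between E16 and P3, and 515, 423 and 212 had an unadjusted p under 0.05 where uniform p-values would give 920.75. The first and second of these were 919 and 877 without P0 control replicate 3, and the third was 320 without P3 CKO replicate 1. DESeq2 called 16, 3 and 9, and limma-voom 0, 0 and 0. From E16 to P0 the difference of log2 fold changes was 1.53 ± 0.29 for Acta2, 1.29 ± 0.26 for Xpnpep2 and 1.76 ± 0.37 for Cbr3, and -3.60 ± 0.74 for AI838599, -2.15 ± 0.58 for Tmem233 and -2.47 ± 0.67 for Cacnb4. From P0 to P3 it was 2.73 ± 0.65 for Ces1f, 0.68 ± 0.17 for Tmem218 and 2.21 ± 0.55 for Asb15, and -0.98 ± 0.22 for Cd300a, -1.26 ± 0.29 for Acta2 and -1.06 ± 0.26 for Xpnpep2. From E16 to P3 it was 2.04 ± 0.50 for Trim34a, 2.36 ± 0.62 for Dclk3 and 1.25 ± 0.35 for Ptger4, and -0.81 ± 0.21 for Trim12c and -3.34 ± 0.87 for Trim34b, while BC065403, with counts at or near 0 in E16 controls and P3 CKO lungs, is given no fold. Adjusted p was 0.387 for Acta2, Xpnpep2, Cbr3 and AI838599 in the first of these comparisons and about 1.00 elsewhere, so by edgeR no gene passed the test of a difference between ages.

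Each library was also scored on the genes changed at the other 2 stages, a measure added after the data were seen. The score is the mean log2 CPM of the 100 genes with the smallest combined p among those higher there minus that of the 100 lower there, set against the control mean of its own stage. All 4 CKO libraries exceeded all 4 controls at each stage, by a mean of 1.22 at E16, 1.59 at P0 and 1.53 at P3, each at p = 0.0286 in a 2-sided exact permutation test, the smallest it allows. The scored genes were not cleared of Gm26825, Gm15459, Gm9008 or genes near Sin3a, so these loci can add to the separation. E16 CKO replicate 4 (0.50) and P3 CKO replicate 1 (0.38) had the lowest CKO scores, against highest control scores of 0.23 and 0.17.

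**Figure D4:**
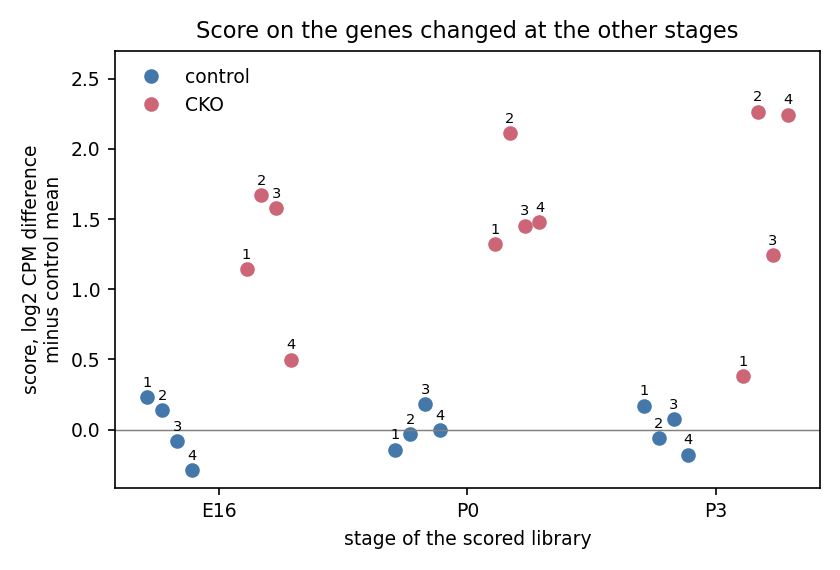
Score of each library (y axis, log2 CPM difference minus the control mean of its stage) on genes changed at the other 2 stages, by stage (x axis), controls in blue, CKO in red, numbered by replicate. CKO libraries range from 0.38 to 2.27 and controls from -0.29 to 0.23.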

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

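The tests of P3 CKO replicate 1 and of the relatives of Gm26825, Gm15459 and Gm9008 were chosen after the results were seen, and the tests of neighbouring genes, of GC content and length and of cell division were written before theirs were.

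Of 373 sets, each a named gene in the 4 libraries of a stage and genotype, 16 held a library far from the other 3. Chance gives about 18.65 for independent sets. These sets share libraries, so their number does not decide whether there is an excess. E16 CKO replicate 4 was low for Rrp12 (20.1 CPM, others 32.2 to 35.4), Shisa3 (6.78, others 14.6 to 16.7) and Fst (0.591, others 1.53 to 1.73), and high for Fgf10 (47.8, others 31.8 to 33.8). In other E16 libraries, Kit was 119 CPM in CKO replicate 3 (others 143 to 147), Cox4i2 was 8.37 in CKO replicate 1 (others 14.0 to 15.4) and Sap30l was 11.6 in control replicate 2 (others 10.8 to 10.9). At P0, Psrc1 was 22.0 CPM in CKO replicate 2 (others 8.97 to 10.2), Nop16 was 32.8 in CKO replicate 1 (others 23.3 to 24.5), Acta2 was 229 in control replicate 1 (others 449 to 490) and Aldoa was 244 in control replicate 4 (others 306 to 312). At P3, Nop16 was 15.2 CPM in CKO replicate 1 (others 20.7 to 21.5), Sesn2 was 8.87 in control replicate 3 (others 12.3 to 12.7), Cox4i2 was 17.5 in control replicate 3 (others 24.2 to 24.7), and in control replicate 2 Foxf1 was 290 (others 197 to 199) and Ly6g was 0.763 (others 0.552 to 0.576).

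P3 CKO replicate 1 lacked much of what the other P3 CKO lungs showed, with a score of 0.381 on the E16 and P0 effects against 1.24 to 2.27 in them and at most 0.17 in controls. A control lung of the kind in the other control libraries is argued against by Gm9008, at 0.178 CPM in this library and 2.81 to 4.73 CPM in P3 controls. Lower depth is argued against by its total of 28.2 M counts, within the range of the other P3 libraries. A weaker deletion in this lung may account for the score, but Sin3a totals did not fall in any P3 CKO lung, so no value measures the deletion and this stays open. A homozygous floxed lung without active Cre also stays open and was not tested.

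Gm26825, Gm15459 and Gm9008 were lower in each CKO library than in any control at E16 and P0, and at P3 this held for Gm9008 alone. Their closest protein-coding relatives were Hspa8 (99.6% and 99.7% identity, chromosome 9, 40800984 to 40810087) and Rnf26 (99.1%, chromosome 9, 44095631 to 44113517), and for 3 of the 3 the relative lay within 25 Mb of Sin3a, so reads of these relatives that differ by strain beside the floxed allele are a candidate source. A strain haplotype that changes neighbouring genes in general predicted more genes near Sin3a with an unadjusted p under 0.05 in one direction at all 3 stages, and that excess was not seen (odds ratio 1.13, Fisher's exact p = 0.715, 2-sided). For lower genes alone, which was not the prediction, the odds ratio was 3.17 (Fisher's exact p = 0.0260), so a local effect on lower genes stays open. Of these lower genes 5 lay near Sin3a, AC160637.1, called at P3, among them. P3 control replicate 1 had 1.28 CPM of Gm26825 and 14.1 CPM of Gm15459, as CKO lungs did, yet 3.59 CPM of Gm9008, while P3 controls 2 to 4, homozygous floxed by title, had 121 to 141 CPM of Gm26825, which reads of a floxed-strain allele do not account for if those titles hold.

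In the stage average MYC targets and ribosome biogenesis genes had a median of 0.27, 9 of 29 passed the test, and the list's call was lost with an estimated correlation (adjusted p = 0.192). A bias by GC content or transcript length is argued against, since the median was 0.29 after its trend was removed. With the mitosis list as a covariate, set to test a larger share of dividing cells, the median stayed at 0.24. The mitosis mean spread mostly at P0 (3.53 to 5.26 log2 CPM, against 6.73 to 6.95 at E16 and 5.47 to 6.03 at P3). There control replicate 3 (5.26) and CKO replicate 1 (4.82), high in thymus markers, were among the highest. This test therefore cannot decide on dividing lung cells as the cause. A direct effect of losing Sin3a in mesenchyme and an altered mix of cells, which whole-lung RNA does not separate, may each contribute and were not tested.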

How the results depend on the processing

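Sample quality weights, the Xist covariate, the fits without libraries high in thymus markers, the counts without genes near Sin3a and everything on the stage average were chosen after the data were seen. The cause of a changed count was not tested except where libraries or genes were left out. Calls per stage were 3, 7 and 2. DESeq2 gave 295 at E16, 190 at P0 and 601 at P3, 42 shared by all stages, and 16, 3 and 9 interactions (E16 to P0, P0 to P3, E16 to P3), and its counts were not set against other splits. One fit of 24 libraries gave 264 at P0, 14 at P3 and 4 shared. The replicate block gave 2 at P0, 0 at P3 and 0 shared, though same-numbered control and CKO lungs deviated together by mean correlations of only -0.29, 0.01 and 0.0047 at E16, P0 and P3, so the numbers do not pair them. For lungs of one identifier prefix, whose meaning is not stated, these means were 0.12, 0.44 and 0.03. At P0 the 4 such pairs were at 0.66, 0.43, 0.68 and -0.0075, against -0.47 to 0.19 (mean -0.14) for the 12 pairs across prefixes. Most P0 lungs of one prefix thus deviated together, which the main fit and the splits do not take into account. Both P0 libraries high in thymus markers, control replicate 3 and CKO replicate 1, share a prefix. The prefix block gave 1 call at P3, 1 interaction from E16 to P0 and 2871 in the average. Quality weights gave 32 at P0, 1162 at P3, 3462 in the average, and 691 instead of 316 for the number of genes with unadjusted p under 0.05 the same way at all 3 stages. The Xist covariate gave 3 at P0 and 121 at P3, no filter 6 at P3, and a minimum log2 change of 1 gave 1 at P3 and 109 in the average. Without the libraries high in thymus markers P0 had 4. Not counting Gm26825, Gm15459, Gm9008 and genes within 25 Mb of Sin3a left 0 at E16, 4 at P0, 0 at P3 and 0 shared.

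Leaving out each library in turn, calls ran from 3 to 188 at E16 (188 without CKO replicate 4), 3 to 6 at P0, 1 to 1625 at P3 (1625 without CKO replicate 1), 981 to 2019 in the average (2019 without P3 CKO replicate 1), 1 to 3 shared (3 without P3 control replicate 1), 223 to 384 with an unadjusted p under 0.05 at all stages, and 0 to 1 for each interaction (1 without P0 control replicate 3 from E16 to P0, and without P3 CKO replicate 4 in the other 2). Sin3a log2 fold change at E16 ran from -0.080 to 0.054, positive at 0.054 without CKO replicate 3, and from 0.02 to 0.16 at P0 and 0.03 to 0.10 at P3. Gene lists called per stage, 46 in all, were 44 to 52 with a library left out, 0 with an estimated correlation and 0 with directional fry, while fry's test of change in either direction called 0, 2 and 2 at E16, P0 and P3. List tests were not run for DESeq2 or the 24-library fit, and unrounded counts not at all, as the table is whole. The P3 correlation with maturation, -0.26, was -0.31 by rank and -0.36 at a log CPM of at least 3, and shares of 0.0571 and 0.114 of the splits were as large.

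The average called 1046 genes without a filter, 1082 with the replicate block, 2161 with DESeq2 and 2087 by combining stage p-values, and 1538 of its 1544 genes were among DESeq2's. Named genes other than Sin3a kept their sign in all alternatives, and Sin3a turned at E16 as given above. In the average 141 of 2200 values lost the call, most often Cldn5 and Eln, at P0 47 of 330 and at P3 9 of 231, while 11, 14 and 25 gained one at E16, P0 and P3 and 8 of 609 did among interactions. Depth limits genes under about 1 CPM.

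The number of genes with an unadjusted p under 0.05 also moved. At E16, 1749 became 944 in one fit of 24 libraries, 1125 with the replicate block, 3049 with quality weights, 1099 without CKO replicate 2 and 1135 without control replicate 3. At P0, 1107 became 2636 in one fit, 2069 with the prefix block and 1795 with quality weights. At P3, 2634 became 1382 in one fit, 4833 with quality weights, 4630 without CKO replicate 1 and 1513 without CKO replicate 2. For interactions, 515, 423 and 212 (E16 to P0, P0 to P3, E16 to P3) became 909, 849 and 564 without a filter and 873, 802 and 466 with the prefix block. The first was 919 without P0 control replicate 3 and 776 without P0 CKO replicate 1. The second was 877 without P0 control replicate 3, 716 without P0 CKO replicate 2 and 695 without P0 CKO replicate 4. The third was 320 without P3 CKO replicate 1 and 139 with a filter of 1 CPM.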

Other observations

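Tests of other splits were written before their results were seen, except those of the number of genes with an unadjusted p under 0.05 at each stage, and the stage average and its list means were added after the data were seen.

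In the stage average, in the list of hypoxia response genes 3 of 26 rose and 0 fell (6 and 1 adjusted over the list alone), and those that rose over all genes were Eno1 (0.38 ± 0.08), Aldoa (0.32 ± 0.07) and Hk2 (0.70 ± 0.21), while the list itself was not called (camera adjusted p = 0.118). Of 31 matrix and elastic fibre genes 2 fell, Eln (-0.44 ± 0.13) and Col6a3 (-0.59 ± 0.14), and 1 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.101). Fst, which encodes the activin antagonist follistatin, rose by 1.00 ± 0.22, Notum, which encodes a secreted WNT inhibitor, fell by 1.08 ± 0.30, and Lyve1, a lymphatic endothelial marker, fell by 0.77 ± 0.16. The lymphatic endothelial list as a whole was not called (camera adjusted p = 0.0816). Acta2 rose by 0.78 ± 0.18 and was the 1 of 24 smooth muscle and myofibroblast genes that did. These genes were chosen after their values were seen, all with adjusted p under 0.05 by edgeR.

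Chance is argued against for the stage average, which called 1544 genes against at most 0 in the other drawn splits (1 of 60 as large). It is also argued against for the 316 genes with an unadjusted p under 0.05 in one direction at all stages (at most 69 otherwise, 1 of 100), and for the 1 gene called at all stages (0 otherwise, 1 of 100). These are the smallest shares the draws can give, they were not adjusted for the number of tests, and the draws ignore the identifier prefix. The 1 gene is Gm9008, and 0 are left without Gm26825, Gm15459, Gm9008 and genes within 25 Mb of Sin3a, or with the replicate block. The number of calls at P0, 7, was larger than in any other split (at most 6, 1 of 35). That is the smallest share 35 splits can give, and shares were not adjusted for the number of tests, so chance is argued against only weakly. The split with 6 parts the P0 libraries by identifier prefix, and 7 genes were called with the prefix as a block. Of the 7 P0 calls 3 are Gm26825, Gm15459 and Gm9008, and 4 are left when these and genes within 25 Mb of Sin3a are not counted, or 3 to 6 when a library is left out. The P0 outcome therefore rests on these loci. Chance cannot be excluded for the number of calls at E16, 3 (3 of 35 splits as large, highest other 4), or at P3, 2 (4 of 35, highest other 4). This concerns their number, not the genes, since the 3 E16 calls Gm26825, Gm15459 and Gm9008 were called at P0 too. Nor can it be excluded for the number of genes with an unadjusted p under 0.05, which was 1749 at E16 (6 of 35 splits, highest other 3272), 1107 at P0 (12 of 35, highest other 2531) and 2634 at P3 (4 of 35, highest other 4225). At P0 the 3 splits along the identifier prefix gave 2531, 1653 and 1356 such genes, and with the prefix as a block the real split gave 2069. It cannot be excluded for the number of lists called, which was 15 at E16 (13 of 35 splits, highest other 25), 14 at P0 (14 of 35, highest other 26), 17 at P3 (10 of 35, highest other 23) and 15 in the average (24 of 60, highest other 25). Splits along the prefix called 21 lists at E16, and 13, 20 and 18 at P0, below the highest of the splits across it (25 and 26), and with the prefix as a block 16 and 14 lists were called. For interactions the splits decide nothing on chance, since each of the 60 gives at least the observed 0. Other draws called up to 2145, 964 and 0 genes (E16 to P0, P0 to P3, E16 to P3), and the reason was not tested.

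Single lists were set against the same 60 draws by their mean change. The MYC and ribosome biogenesis list (0.33, largest other 0.20) and the SIN3 and histone deacetylase list (0.12, largest other 0.08) were matched by no other draw in mean or in camera p. Neutrophil (-0.56, 0.41), alveolar fibroblast (-0.29, 0.21), pericyte (-0.27, 0.19), interferon response (-0.31, 0.29), cytosolic ribosomal protein (0.21, 0.17) and FGF signalling genes (-0.15, 0.14) were matched in mean by no other draw, but in camera p by some. Endothelial (-0.29, 0.30), p53 target (0.13, 0.15), alveolar type 1 (-0.26, 0.31), alveolar type 2 (-0.18, 0.27) and mesothelial genes (-0.24, 0.26) were matched in mean by 2 of 60, the observed one included. Mitosis (0.18, largest other 0.41) and DNA replication genes (0.15, largest other 0.29) were matched in mean by 11 and 10 of 60, the observed one included.

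One hypothesis was that CKO lungs resemble younger or older lungs. The CKO effect at each stage was correlated across genes with the change in controls between the other 2 stages. That change can hold library batch as well as age, and by title P3 controls differ in genotype from the others. For the E16 and P3 effects it includes P0 control replicate 3, high in thymus markers. Pearson r was 0.04 at E16 (33 of 35 splits as large, highest other 0.303), -0.14 at P0 (4 of 35, highest other 0.186) and -0.26 at P3 (1 of 35, highest other 0.229). By this measure no other split was as large at P3 alone, and 1 of 35 is the smallest share the splits can give. At P3 chance cannot be excluded by rank (-0.31, a share of 0.0571 of the splits as large) or at a log CPM of at least 3 (-0.36, a share of 0.114). The P3 values have the sign of a profile shifted toward younger lungs, but the hypothesis was left open at P3 and has no backing at E16. At P0 the value was -0.19 by rank (other splits up to 0.28) and -0.23 at a log CPM of at least 3 (up to 0.24). Chance is thus not excluded at P0 by any of these measures.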
